A study of Mus musculus with 8 samples.

How the data were processed

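Linear and circular RNA were measured in 8 libraries of isolated mouse renal proximal tubules, 2 at each of 0, 24, 48 and 72 h after cisplatin. Per the labels' protocols, proximal tubular cells were isolated from renal cortex, total RNA was taken up in Trizol, ribosomal RNA was removed with a Ribo-Zero kit, and libraries were made with a kit that the labels name as one for small RNA. The series' design text calls the duplicates biological but does not say that they came from separate animals, so p-values measure the spread between these samples.

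The linear RNA values were FPKM (fragments per kilobase of gene and mapped depth), made by the authors and named so per the file headers, with 1 value per gene row and library. The circRNA table held whole-number counts per back-splice position pair, deposited by the authors without normalization, where a back-splice is the junction that closes a circle. Bowtie 0.12.2, TopHat2, Cufflinks and the mouse build mm10 are named per the submitters' processing notes, with no role or order; the circRNA caller is not given in the sources used here. Columns carry the letters a and b where the labels carry replicate numbers, so each column was assigned to its time group only, and libraries are named by time and letter. The gene and circRNA tables were joined on these column names. Another 8 columns of the circRNA table, which carry the same library names with a second measure, were not used here.

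Of 21874 gene rows, 19742 matched a symbol through their gene identifiers and 1732 were named as new loci. Many rows cover more than their gene. Rows were set against RefSeq gene spans of the same assembly, with a tolerance of 2000 bases. Of these, 14480 kept to their own gene, and 1515 also spanned at least 1 protein-coding gene with no row of its own (merged rows). Another 2925 reached past their gene or lay nested with another, and 2954 had no RefSeq span. Overlap with a gene that has its own row was not looked for, so rows of any class can overlap another row. Values of a merged row cannot be split between its genes, and whether fragments were counted by strand is not given in the sources used here. Genes named in the text with a merged row are marked. Rows that reached past their gene or lay nested with another are marked for only some named genes. Positions given for genes are those of their rows.

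Rows with at least 1 FPKM in at least 2 of the 8 libraries were tested, 10757 in all. limma 3.58.1 was run in R 4.3.3 with an intensity trend and robust empirical Bayes on log2(FPKM + 1), in 1 fit of all 8 libraries so that the 4 groups shared an estimate of the spread. Fold changes are on that scale, which understates the change of genes with low FPKM. Values in FPKM do not give the depth of the linear RNA libraries, so depth and counting intervals are unknown for them. A row listed at exactly 0 can be a failed estimate, so such rows are given by library and without a fold change. circRNAs with counts above 0 in at least 4 of the 8 libraries, 1574 of 2163, were tested with the quasi-likelihood test of edgeR 4.0.16 (TMM normalization, robust). A circRNA was assigned to a host when it lay inside exactly 1 protein-coding gene, which held for 1872; 13 lay inside more than 1 and 278 inside none. Each circRNA was set against its host row with limma on log2(normalised count + 1) minus log2(FPKM + 1) in each library. All tests are 2-sided with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. Values of 1 number per library were compared by an exact permutation test over the 105 assignments of 8 libraries to 4 groups of 2, whose smallest p is 0.00952; no p is given for 2 libraries against 2.

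Gene lists for tubule segments, other kidney and blood cell types, injury, stress and metabolism, 37 in all, were written from textbook knowledge before the data were examined, as were the tests, the rule for named genes and the first set of alternative settings. Of 608 list members, 531 had a row under their own name and 486 were tested. The 33 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over 99 tests of 33 lists in 3 contrasts, and again with a correlation estimated for each list and with fry, which tests the list's own genes without comparing them with others. With camera 60 of the 99 passed, 30 higher and 30 lower; with an estimated correlation 0 passed; with fry 90 passed for a shift in 1 direction and 99 for any change. Named genes are, for each contrast with 0 h, the 8 largest rises and 8 largest falls past the threshold with non-overlapping libraries (symbols of predicted genes left out), up to 4 members of each described list by smallest p, and Havcr1, Lcn2, Cdkn1a, Slc34a1, Lrp2, Umod and Slc22a2; for successive times, up to 4 each way; for circRNAs, up to 5 each way and the 5 with the highest mean count. Some genes that this rule names are not reported here.

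The main procedures were tested on simulated data for 72 h against 0 h. Of 100 genes changed by 0.5 on the log2 scale limma recovered 37.0% over 10757 rows, and of 100 changed by 1 it recovered 85.0%, with 9 false calls. Over 1574 circRNAs edgeR recovered 9.0% of 100 changed by a log2 of 1 and 32.0% of 100 changed by 2, with 1 false call; with a mean count of at least 10 it recovered 31.0% of 29 and 76.7% of 30. The limma test of circRNA against host recovered 15.0% of 100 changed by a log2 of 2, with 3 false calls. An edgeR fit with the host's FPKM as an offset recovered 41.0% with 16 false calls, and 11 calls in an unchanged contrast, so its calls include many false ones. camera recovered 3 of 3 changed lists of 16 genes with 0 false calls. The simulated genes varied independently of each other, so this does not test whether the preset correlation is right for the data. camera with an estimated correlation was not tried on simulated data. It rests on the few residual degrees of freedom that 2 libraries per group leave, and its lowest adjusted p for any list was 0.129. A call lost with it can thus reflect low power and does not show that a list was unchanged.

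circRNA totals ran from 13603 to 21024 counts per library, and the share that 3 counts make, the limit a count of 0 allows, from 0.0143% to 0.0221%. Such limits and 95% intervals cover counting error only. Alternatives tried were other pseudocounts, filters, scalings and fits, leaving out each library in turn, and, added after the data were seen, rows that keep to their own gene, DESeq2 1.42.0, circRNAs with both ends in 1 gene, the offset fit, a fit with the column letter as a block, and list tests without mt-Co1. No check of GC content was made, since no genome sequence was used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.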

Results

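The series followed linear and circular RNA in proximal tubules isolated from the kidneys of C57BL/6 mice given 30 mg/kg cisplatin, a platinum drug that injures this part of the nephron. There were 4 groups of 2 libraries, at 0, 24, 48 and 72 h. The 0 h group, for which no dose is listed, was the control for every comparison with 0 h. The deposited FPKM values totalled 448667 and 452114 in 0 h libraries a and b, 375186 and 348891 at 24 h, 314173 and 317983 at 48 h, and 351353 and 354145 at 72 h. The number of gene rows above 0 was 15629 and 15781 at 0 h, 16171 and 16687 at 24 h, 17704 and 17656 at 48 h, and 16717 and 16707 at 72 h. The groups differed with an exact permutation p of 0.00952, the smallest the design allows. Mitochondrially encoded rows made up 25.5% and 24.7% of the FPKM at 0 h and 20.2% to 21.8% in the other libraries (exact permutation p = 0.0571). Most of the difference at 24 and 48 h lay in mt-Co1, which was listed at 0 there: without it the share was 22.1% and 21.6% at 0 h, 20.2% to 21.8% at 24 and 48 h, and 17.7% in both 72 h libraries (exact permutation p = 0.0571). The circRNA counts totalled 13603, 18171, 17057, 17348, 21024, 17048, 16318 and 15455 in time order, with a before b in each group (exact permutation p = 0.562).

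Libraries of a group resembled each other more than those of other groups. Pearson's r of log2(FPKM + 1) across genes was 0.994 within the 0 h group, 0.989 at 24 h, 0.990 at 48 h and 0.992 at 72 h, against at most 0.978 between groups; genes are not independent replicates. The first principal component held 65.0% of the variance and the second 24.1%. The circRNA counts of each duplicate pair differed by more than sampling noise, with chi-square over degrees of freedom from 1.39 to 2.20, so no pair was treated as 1 library deposited more than once.

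At 24 h against 0 h, stress and injury genes were higher and genes of proximal tubule function were lower. Cdkn1a, the p53-controlled inhibitor of cyclin-dependent kinases (chromosome 17, 29086268 to 29100722, mm10), rose from 1.505 ± 0.235 to 53.3 ± 5.27 FPKM (SD, n = 2), a log2 fold change of 4.44 ± 0.0963 (SE). Lcn2, which encodes the injury marker lipocalin 2 and whose row also spans 1110008P14Rik (chromosome 2, 32377097 to 32388341), rose from 19.3 ± 0.439 to 106 ± 6.79 FPKM. Slc34a1, the sodium-phosphate cotransporter of the brush border (chromosome 13, 55398131 to 55414695), fell from 1440 ± 61.7 to 572 ± 60.9 FPKM, and Lrp2, the endocytic receptor megalin (chromosome 2, 69424340 to 69588277), from 1305 ± 177 to 489 ± 105.05 FPKM. Havcr1, the kidney injury marker KIM-1 (chromosome 11, 46682647 to 46780361), was still low at 2.50 ± 0.0533 FPKM, from 0.297 ± 0.0437 at 0 h. The rows of Cdkn1a, Lrp2 and Havcr1 reached past their gene or lay nested with another, and that of Havcr1 overlaps the row of Timd2. Slc22a2, the organic cation transporter that takes up cisplatin (chromosome 17, 12583863 to 12628366), fell from 115 ± 0.826 to 56.3 ± 2.09 FPKM. All 6 changes had adjusted p from 1.9e-08 to 0.00020 in limma with Benjamini-Hochberg adjustment, and both 24 h libraries lay beyond both 0 h libraries.

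The largest rise at 24 h was in a merged row named Krt12 that also spans Krt20, a keratin of injured epithelium, by a log2 of 6.93. It was followed by Cdkn1a, the stress transcription factor Atf3 (4.15), Plk2 (3.63) and the urokinase receptor Plaur (3.60). The rows of Atf3 and Plk2 also reached past their gene or lay nested with another. Next came Tnfrsf12a in a row that also spans Thoc6 (3.59), the ephrin receptor Epha2 (3.56) and the metal-binding metallothionein Mt2 (3.45). The largest falls with a fold change were in Timd2 (-2.95), Tcaim (-2.90), Pzp (-2.88) and Gatm, the first enzyme of creatine synthesis (-2.84). Close to these were Lrrc8d in a row that also spans Gm42166 (-2.79), Hsd11b2, which inactivates glucocorticoids (-2.70), and Klf15 (-2.70). The mitochondrial gene mt-Co1 was listed at 0 in both 24 h and both 48 h libraries, against 19149 and 18120 FPKM in the 0 h libraries and 16678 and 17071 in the 72 h libraries. In all, limma with Benjamini-Hochberg adjustment called 7076 of 10757 rows, 2772 higher and 4304 lower. The split depends on the scaling: limma called 3451 higher and 3619 lower with the same median set in every library, and 3241 and 3544 after quantile normalisation. Of the 7076, 585 were higher and 1001 lower by at least 2-fold. The libraries of the 2 groups did not overlap in 8797 rows, against 33.3% by chance. The median change of all tested genes was -0.12, so medians of gene lists are given from here on relative to the median of all tested genes, and changes of single genes as measured.

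Several lists of injury, stress, inflammation and matrix genes were higher at 24 h in camera at its preset correlation. Of 16 tested tubular injury markers 14 rose and 1 fell (median 1.52), led by the tight junction gene Cldn4 (3.23), Lcn2 (2.40), Timp1 (2.87) and Krt18 (2.68). Of 29 p53 target genes 23 rose and 3 fell (median 1.53), with Btg2 at 3.25 and Trp53inp1 at 2.65, and all 16 heat shock and immediate-early genes rose (median 1.52), among them Klf6 (2.95), Jun (2.92) and Fos (3.29). camera gave these lists adjusted p of 2.2e-07, 4.2e-10 and 1.3e-09, and each call was lost with an estimated correlation, at adjusted p = 0.129, 0.143 and 0.151. Cytokines, chemokines and NF-kB targets rose in 12 of 21 and fell in 1 (median 0.67; Socs3 2.70, Cxcl2 1.30, Ccl2 1.19), and interferon-stimulated genes rose in 15 of 20 and fell in 1 (median 0.72; Ifit1 1.89, Gbp2 1.26). camera gave adjusted p of 9.2e-05 and 2.9e-05. These became, in camera, adjusted p = 0.151 and 0.248 with an estimated correlation. Extracellular matrix and fibrosis genes rose in 9 of 18 and fell in 5 (median 0.54; Ccn1 1.74, Vim 1.69), with camera adjusted p = 0.0107, and adjusted p = 0.350 with an estimated correlation. Of 19 genes of the unfolded protein and integrated stress response 9 rose and 6 fell (median 0.37), with Atf3, Ppp1r15a (2.79) and Ddit3 (2.78) highest; camera gave adjusted p = 0.049996, and adjusted p = 0.370 with an estimated correlation. That last call was lost when any of 6 libraries, 0 h a, 24 h a, 48 h a, 48 h b, 72 h a or 72 h b, was left out, at camera adjusted p from 0.0501 to 0.0655. It was also lost in camera with the same median set in every library (0.0747) and with a pseudocount of 0.1 (0.0503) or mt-Co1 left out (0.0501).

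Proximal tubule genes fell together. Of 28 transporters and endocytic receptors 25 fell and 1 rose, or 26 fell when adjusted over the list alone (median -1.10), led by the amino acid transporter Slc7a8 (-2.29) and the sulfate transporter Slc26a1 (-2.02). All 9 markers of the S1 and S2 segments fell (median -1.21; Gatm -2.84), as did 9 of 10 markers of the S3 segment, with 1 higher (median -1.12; Slc16a9 -2.39), and 10 of 11 tubule transcription factors, with 1 higher (median -1.02; Maf -1.87, Hnf4a -1.71). camera gave adjusted p of 4.3e-07, 0.00045, 0.0060 and 0.0025 for the 4 lists. The lists then had, in camera, adjusted p = 0.191, 0.248, 0.29996 and 0.302 with an estimated correlation. In metabolism, 21 of 25 genes of fatty acid oxidation and the peroxisome fell and 2 rose, or 22 fell when adjusted over the list alone (median -0.77; Ehhadh -1.78, Cpt2 -1.49). Of 28 nuclear genes of the TCA cycle and respiratory chain 23 fell and 2 rose (median -0.30; Ogdh -1.61, Idh2 -1.30), and 5 of 6 gluconeogenesis genes fell (median -1.52; G6pc -2.46, Pck1 -2.23). camera gave adjusted p of 8.4e-05, 0.0017 and 0.0068. In camera the lists had adjusted p = 0.248, 0.320 and 0.200 with an estimated correlation. The fatty acid list's call was lost over rows that keep to their own gene (camera adjusted p = 0.0539).

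Markers of other cell types moved at the same time. For these lists and the proximal tubule lists, at every time, a changed cell make-up of the isolate cannot be told from changed expression. Neutrophil markers rose in 6 of 8 (median 0.89; S100a8 3.34, S100a9 2.91) and podocyte markers in 6 of 10, with 1 lower (median 0.68; Podxl 0.58, Wt1 0.61), at camera adjusted p of 0.00043 and 0.0079. They then stood, in camera, at adjusted p = 0.151 and 0.248 with an estimated correlation. All 8 thick ascending limb markers fell (median -1.05; Sostdc1 -1.65, Kcnj1 -1.59), as did 9 of 10 distal convoluted tubule markers (median -0.94; the Klotho gene Kl -1.73, Slc12a3 -1.37) and 8 of 10 intercalated cell markers (median -1.42; the anion exchanger Slc4a1 -2.49). camera gave adjusted p of 0.0030, 0.0025 and 0.0058. camera then gave adjusted p = 0.164, 0.191 and 0.191 with an estimated correlation. Macrophage and monocyte markers were higher in 5 of 10 and lower in 1, and the list did not pass (camera adjusted p = 0.109), except with 0 h library a left out (camera adjusted p = 0.0453). Endothelial markers (camera adjusted p = 0.499), regulated cell death (0.165), DNA replication and S phase (0.402) and mitochondrially encoded genes (0.0947, or 0.277 without mt-Co1, whose listing at 0 entered this test) did not pass at 24 h. Apart from the exceptions named, counts adjusted over the list alone were those over all genes tested for each list named at 24 h.

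**Figure D1:**
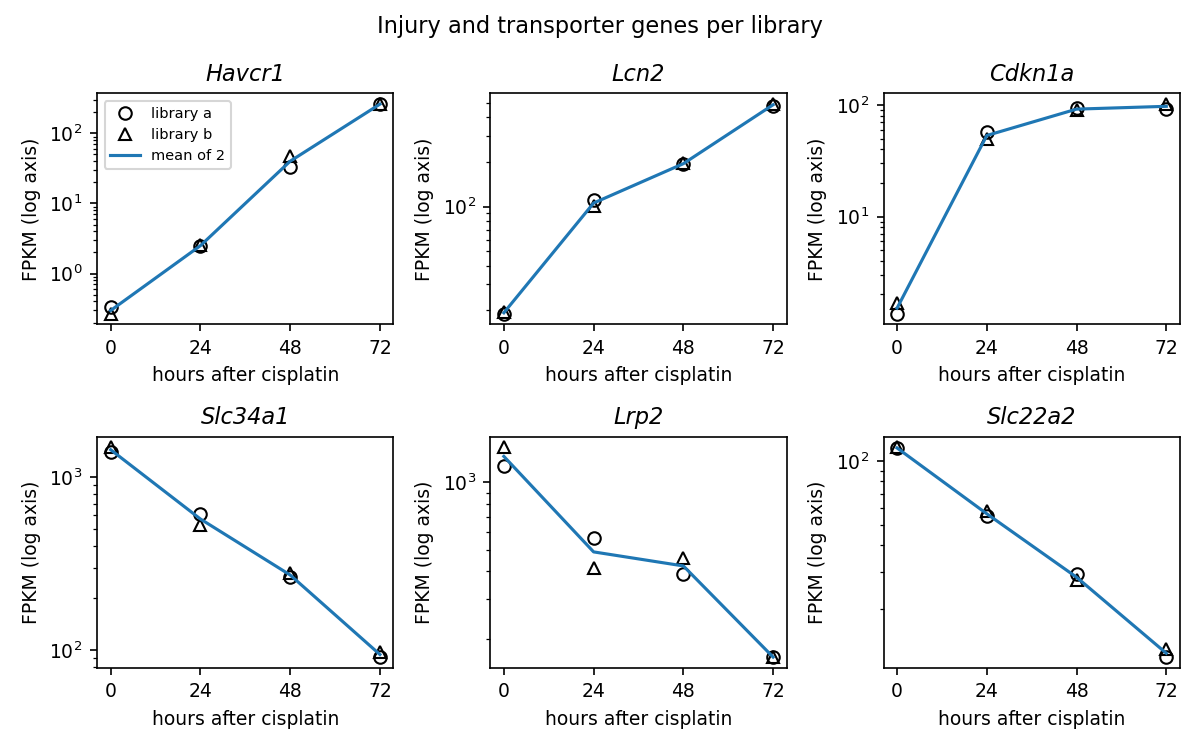
FPKM of 6 genes in each library (log axis) against hours after cisplatin; circles are library a, triangles library b, and the line joins the means of the 2 libraries. Havcr1 reached 261 FPKM at 72 h from 0.297 at 0 h, and Slc34a1 fell from 1440 to 94.2 FPKM.

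At 48 h injury genes stood above, and proximal tubule genes below, their 0 h levels. Havcr1 stood at 40.0 ± 10.1 FPKM (log2 fold change 4.96 ± 0.141, SE) and Cdkn1a at 91.9 ± 2.84 (5.22 ± 0.0963). Lcn2 rose to 195 ± 3.06 FPKM (3.27). Slc34a1 fell to 272 ± 9.48 FPKM (-2.40), Lrp2 to 423 ± 50.1 (-1.62) and Slc22a2 to 28.3 ± 1.22 (-1.99), with limma adjusted p from 6.6e-09 to 8.0e-05 over these 6 genes. The other largest rises were in the row of Krt12 and Krt20 (7.33), Mt2 (4.21), Cldn4 (4.10), Plaur (4.08), Atf3 (3.93) and Sprr1a, a cornified envelope protein (3.74). The furthest falls with a fold change were in Cyp2d9, whose row also spans Cyp2d12 (-4.22), Timd2 (-3.97) and the alpha globin row Hba-x, which also spans Hba-a1 and Hba-a2 (-3.94). They were followed by the glucose-6-phosphatase gene G6pc (-3.78), Gatm (-3.72), Clec2h (-3.60) and Acadsb, whose row also spans Pstk (-3.51).

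limma with Benjamini-Hochberg adjustment called 7585 rows at 48 h, 3061 higher and 4524 lower, or 3827 and 3885 with the same median set in every library and 3678 and 3769 after quantile normalisation. Of the 7585, 783 and 1569 changed by at least 2-fold. Libraries did not overlap in 9299 rows, against 33.3% by chance. The median of all tested genes was -0.13. The 48 h libraries also had the most rows above 0, which need not mean that more genes were expressed; the cause was not tested. Of 1325 rows of olfactory and vomeronasal receptor genes, which kidney tubules are not known for, 352 and 314 were above 0 at 48 h, against 34 and 38 at 0 h, 71 and 91 at 24 h, and 101 and 90 at 72 h.

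By list, tubular injury markers rose in 15 of 16 and fell in 1 (median 2.45; Timp1 3.30, Krt18 2.99). The p53 targets rose in 23 of 29 and fell in 2 (median 2.12; Btg2 3.69, Trp53inp1 3.18), and heat shock and immediate-early genes rose in 15 of 16 (median 1.74; Fos 2.88, Jun 2.75). camera gave adjusted p of 9.6e-09, 4.2e-10 and 1.8e-08. In camera they were adjusted p = 0.129, 0.143 and 0.167 with an estimated correlation. Cytokines, chemokines and NF-kB targets rose in 19 of 21 and fell in 1 (median 1.32; Ccl2 2.66, Il1b 2.53). Interferon-stimulated genes rose in 16 of 20, with 1 lower (median 1.11; Ifit1 2.10, Rsad2 1.20), and extracellular matrix and fibrosis genes in 16 of 18 (median 1.14; Ccn1 2.27, Vim 1.56). camera gave adjusted p of 2.6e-07, 1.0e-05 and 1.6e-06. These became, in camera, adjusted p = 0.135, 0.248 and 0.200 with an estimated correlation. Of 20 genes of regulated cell death 11 rose and 5 fell (median 0.51; Mcl1, which blocks apoptosis, 1.37, Gpx4, which blocks ferroptosis, -0.79), with camera adjusted p = 0.049996, and adjusted p = 0.221 with an estimated correlation. That call was lost with any of 0 h library b, 48 h library a, 72 h library a or 72 h library b left out (camera adjusted p from 0.0546 to 0.0575) and with the same median set in every library (0.0713) or mt-Co1 left out (0.0501).

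The proximal tubule lists were lower at 48 h than at 0 h. Transporters and endocytic receptors fell in 26 of 28 and rose in 1 (median -1.78; Slc5a8 -2.14, Cubn -2.35). All 9 S1 and S2 markers fell (median -2.27; Slc5a12 -2.58), all 10 S3 markers fell (median -2.03; Slc7a13 -2.39), and 10 of 11 transcription factors fell (median -1.16; Hnf4a -2.02). camera gave adjusted p of 1.3e-08, 0.00013, 0.00016 and 0.0025. The lists then had, in camera, adjusted p = 0.191, 0.244, 0.220 and 0.302 with an estimated correlation. Fatty acid oxidation and peroxisome genes fell in 24 of 25 (median -1.40; Acsm1 -2.40); the 1 that rose was Pdk4 (1.96), a kinase that restrains pyruvate oxidation. Nuclear TCA cycle and respiratory chain genes fell in 26 of 28, or 27 when adjusted over the list alone (median -0.71; Idh2 -2.04, Sdhb -1.09), and all 6 gluconeogenesis genes fell (median -2.58; Pck1 -2.92, Slc37a4 -2.51). camera gave adjusted p of 2.2e-06, 1.0e-06 and 0.0025. In camera the lists had adjusted p = 0.200, 0.220 and 0.191 with an estimated correlation.

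Among other cell types at 48 h, all 8 neutrophil markers rose (median 1.30; Il1r2 1.90, Retnlg 2.30) and 8 of 10 podocyte markers rose, with 1 lower (median 0.72; Wt1 0.81, Clic5 -0.50), at camera adjusted p of 0.00031 and 0.0116. They then stood, in camera, at adjusted p = 0.151 and 0.251 with an estimated correlation. All 8 thick ascending limb markers fell (median -1.32; Slc12a1 -1.36), with 9 of 10 distal convoluted tubule markers (median -1.76; Calb1 -2.01) and 8 of 10 intercalated cell markers (median -1.12; Atp6v1b1 -1.87). camera gave adjusted p of 0.0016, 0.0026 and 0.0101. camera then gave adjusted p = 0.151, 0.191 and 0.200 with an estimated correlation. The unfolded protein and integrated stress response (camera adjusted p = 0.172), macrophage and monocyte (0.0947), endothelial (0.0919), S phase (0.0575) and mitochondrially encoded (0.0708, or 0.197 without mt-Co1, listed at 0 here too) lists did not pass. Leaving out single libraries brought some of these past the threshold: 0 h a for macrophages (camera adjusted p = 0.0375), 48 h b for endothelium (0.0440) and mitochondrially encoded genes (0.0399), and 0 h b, 24 h a or 24 h b for S phase (0.0453 to 0.0490).

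At 72 h, Havcr1 was the most raised gene, at 261 ± 2.01 FPKM (log2 fold change 7.66 ± 0.141, SE), and immune and matrix genes stood higher than at 0 h alongside the injury genes. After the row of Krt12 and Krt20 (7.41) came the calcium-binding protein gene S100a6, whose row also spans S100a7a (5.66), and the chitinase-like gene Chil3, whose row also spans Chil4 (5.51). They were followed by Mt2 (5.49), Cdkn1a (5.30), the metalloproteinase inhibitor Timp1 (5.03) and Akap12 (4.91). Lcn2 reached 486 ± 8.13 FPKM (4.59). Slc34a1 fell to 94.2 ± 4.92 FPKM (-3.92), Lrp2 to 166 ± 0.684 (-2.96) and Slc22a2 to 12.4 ± 0.768 (-3.11). The globin rows fell furthest, Hba-x from 413 ± 107 to 2.82 ± 1.86 FPKM (-6.83) and Hbb-bs, which also spans Hbb-bt, from 374 ± 5.88 to 4.49 ± 0.433 FPKM (-6.10). Spp2 (-4.83), the brush border protease Mep1b (-4.68), Gatm (-4.61), Clec2h (-4.50), Cyp2d26, whose row also spans Cyp2d12 (-4.44), and Fam151a (-4.39) came next. These genes had limma adjusted p from 6.2e-10 to 0.00106.

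limma with Benjamini-Hochberg adjustment called 7535 rows at 72 h, 4049 higher and 3486 lower, or 3732 and 3847 with the same median set in every library and 3730 and 3681 after quantile normalisation. Of the 7535, 1273 and 1210 changed by at least 2-fold. Libraries did not overlap in 9318 rows, against 33.3% by chance. The median of all tested genes was 0.07. Umod, the uromodulin gene of the thick ascending limb, had no row of its own, and rows named Pik3c2a and Gp2 both span it. The Gp2 row stood at 1431 FPKM at 0 h, 638 at 24 h, 295 at 48 h and 488 at 72 h, and the part due to Umod cannot be told.

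By list at 72 h, injury markers rose in 15 of 16 (median 3.18; Cldn4 4.39, Anxa2 3.39). The p53 targets rose in 23 of 29, with 1 lower (median 1.99; Btg2 3.98, Phlda3 3.89), and heat shock and immediate-early genes in 15 of 16, with 1 lower (median 1.94; Klf6 2.66). camera gave adjusted p of 3.9e-08, 1.8e-07 and 2.4e-06. In camera they were adjusted p = 0.129, 0.151 and 0.191 with an estimated correlation. Cytokines, chemokines and NF-kB targets rose in 20 of 21 and fell in 1 (median 1.65; Socs3 3.50, C3 3.49). Interferon-stimulated genes rose in 17 of 20, with 1 lower, or 19 when adjusted over the list alone (median 1.16; Irf7 1.90, Oasl2 1.71), and extracellular matrix and fibrosis genes in 17 of 18 (median 2.14; Ccn1 2.87, Vim 2.75). camera gave adjusted p of 1.0e-06, 8.4e-05 and 2.3e-07. These became, in camera, adjusted p = 0.135, 0.251 and 0.191 with an estimated correlation. Regulated cell death genes rose in 12 of 20 and fell in 2, or 3 when adjusted over the list alone (median 0.91; Acsl4 1.89, Ripk3 1.82), and genes of DNA replication and S phase rose in 13 of 16 and fell in 1 (median 0.71; Rrm2 1.75, Mcm4 1.01). camera gave adjusted p of 0.0155 and 0.0052. The lists then had, in camera, adjusted p = 0.191 and 0.221 with an estimated correlation.

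Immune and vascular markers rose with these lists at 72 h. Neutrophil markers rose in 8 of 8 (median 2.39; S100a8 4.52, Il1r2 3.53), macrophage and monocyte markers in 9 of 10 (median 1.36; Itgam 3.14, Lyz2 2.20). Endothelial markers rose in 10 of 12 (median 0.96; Flt1 1.98, Cdh5 1.51) and podocyte markers in 8 of 10, with 1 lower, or 9 when adjusted over the list alone (median 0.76; Synpo 1.34, Clic5 -0.78). camera gave adjusted p of 0.00013, 0.0023, 0.0019 and 0.0351. In camera the lists had adjusted p = 0.151, 0.248, 0.248 and 0.309 with an estimated correlation. The podocyte call was lost over rows that keep to their own gene (camera adjusted p = 0.0843). Among 3 tested erythroid genes, too few to test as a list, Hbb-bs (-6.10) and Alas2 (-1.96) fell and Slc25a37 did not pass (-0.09, limma adjusted p = 0.616). Of 13 lymphocyte genes, all with a row of their own, only 2 reached 1 FPKM in at least 2 libraries and were tested. These were Gzma at 0.19 (limma adjusted p = 0.293) and Cd79a at 1.24 in a row that spans many other genes and is not read as a lymphocyte signal.

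The proximal tubule lists and some lists of other tubule segments and of metabolism were lower at 72 h than at 0 h. Proximal tubule transporters and endocytic receptors fell in 27 of 28 and rose in 1 (median -2.65; Slc5a8 -3.06, Cubn -3.05). All 9 S1 and S2 markers fell (median -3.08), all 10 S3 markers fell (median -2.62; Slc7a13 -4.38), and transcription factors fell in 7 of 11 and rose in 1 (median -1.14; Hnf4a -2.36, Maf -1.93). camera gave adjusted p of 1.7e-11, 7.3e-06, 7.0e-06 and 0.0184. They then stood, in camera, at adjusted p = 0.151, 0.200, 0.191 and 0.364 with an estimated correlation. Fatty acid oxidation and peroxisome genes fell in 22 of 25 and rose in 1 (median -1.11; Acsm2 -3.17), all 28 nuclear TCA cycle and respiratory chain genes fell (median -1.10; Idh2 -2.03, Atp5a1 -1.28). All 6 gluconeogenesis genes fell (median -2.68; G6pc -4.34), and mitochondrially encoded genes fell in 7 of 10 and rose in 1, or 8 fell when adjusted over the list alone (median -0.46; mt-Nd3 -1.34, mt-Nd2 -0.69). camera gave adjusted p of 1.4e-06, 1.3e-09, 0.00077 and 0.0341. camera then gave adjusted p = 0.200, 0.191, 0.179 and 0.251 with an estimated correlation. Thick ascending limb markers fell in 7 of 8 (median -1.04; Sostdc1 -1.53) and all 10 distal convoluted tubule markers fell (median -2.25; Kl -3.52, Calb1 -2.68), at camera adjusted p of 0.0022 and 9.2e-05, and adjusted p = 0.151 with an estimated correlation for both. Intercalated cell markers, lower in 5 of 10 and higher in 1, did not pass (camera adjusted p = 0.0947), nor did the unfolded protein and integrated stress response (0.277); whether these lists differed between times was not tested.

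Several lists passed at none of the 3 times. Genes of cisplatin transport and glutathione conjugate handling went both ways, with Mt1 (4.04) and Mt2 higher and Slc22a2 and Ggt1 (-3.07) lower at 72 h; of 11, 9 fell and 2 rose at 24 h, 8 and 2 at 48 h, and 7 and 3 at 72 h. camera gave adjusted p of 0.0750, 0.0718 and 0.0588 in time order; the list passed at 24 and 48 h with the same median set in every library (0.0408 and 0.0398) and at 72 h with 0 h library b or 72 h library a left out (0.0482 and 0.0476). NRF2 targets, of the oxidative stress response, rose in 10, 9 and 13 of 21 (at 72 h Srxn1 2.38, Hmox1 1.83, Me1, whose row also spans Cep162, -1.52) and fell in 6, 8 and 6, with camera adjusted p of 0.0947, 0.224 and 0.135. Glycolysis genes fell in 10, 11 and 8 of 16 and rose in 3, 4 and 7, with Hk2 at 1.84 and Pfkm at -1.67 at 72 h, and camera adjusted p of 0.224, 0.246 and 0.874. camera also gave no call for G2 and mitosis (adjusted p = 0.952, 0.689 and 0.104), except over rows that keep to their own gene at 72 h (0.0176), for DNA repair (0.661, 0.745 and 0.414), for the circadian clock (0.453, 0.402 and 0.854) or for circRNA biogenesis and turnover factors (0.440, 0.115 and 0.104). Of their members, the nuclease gene Ercc1 rose by 2.70 and the clock output gene Hlf fell by 2.04 at 72 h, and Ythdc1 rose by 1.23 at 24 h. Principal cell markers (camera adjusted p = 0.456, 0.745 and 0.793) and interstitial and mesangial markers (0.172, 0.0511 and 0.0947) did not pass either, though the latter passed at 48 h with 0 h library a or 48 h library a left out (0.0271 and 0.0369). Lists of stress-linked long noncoding RNAs and of small structural RNAs had 0 measured members under their own names. Median, mean and camera direction differed in sign, on the scale before the shift, for glycolysis and the clock at 72 h, the unfolded protein response, G2 and mitosis, DNA repair and the clock at 48 h, and S phase, DNA repair, endothelium and the clock at 24 h, none of which passed.

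**Figure D2:**
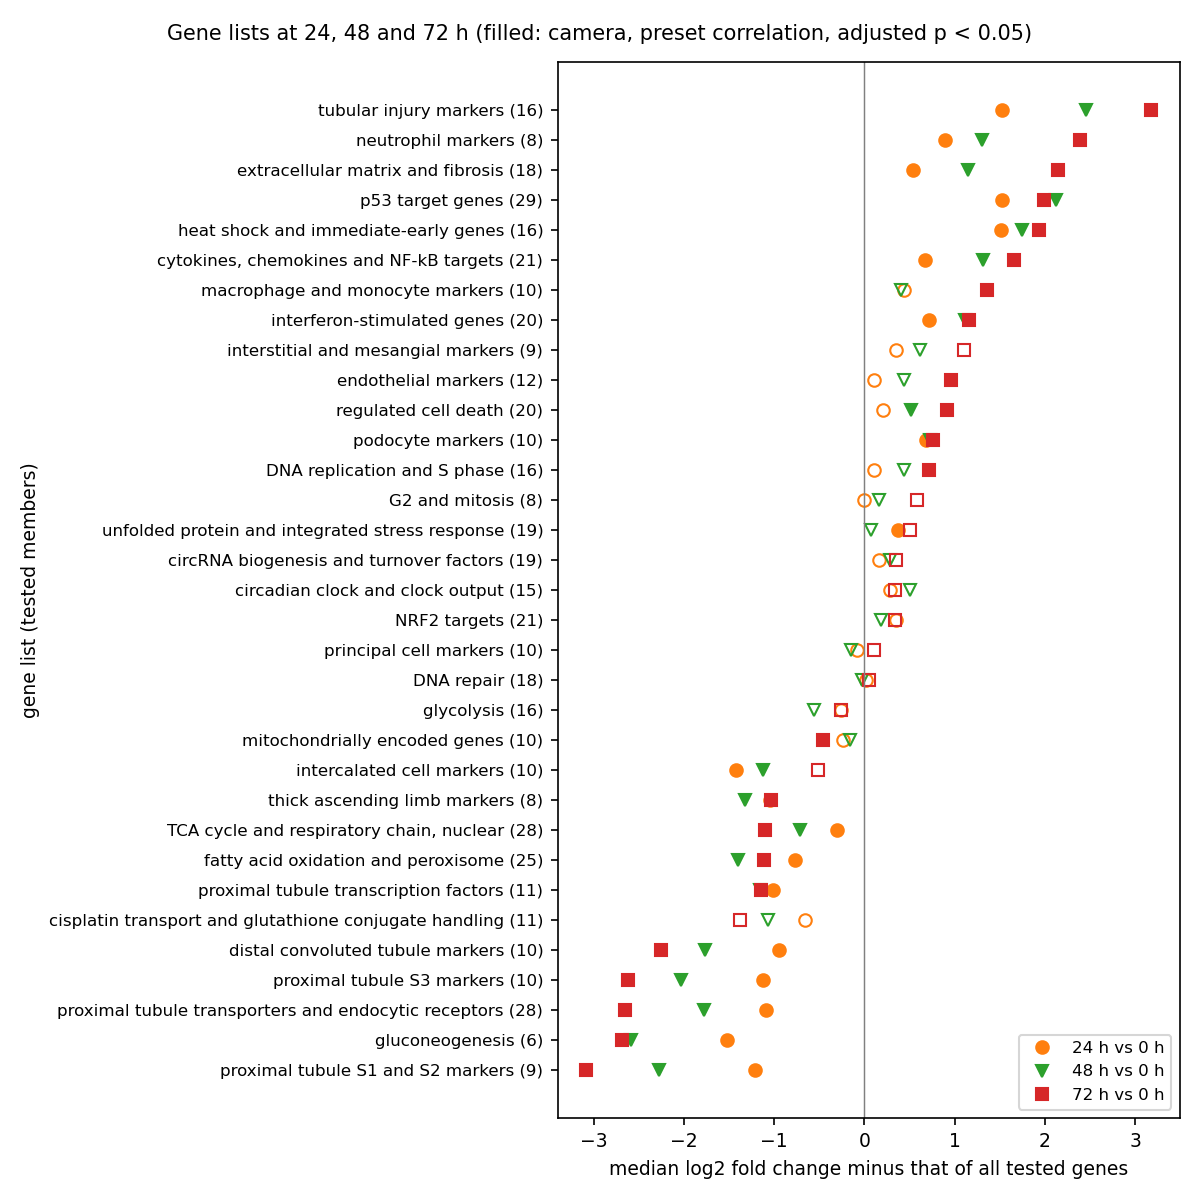
Median log2 fold change of the tested members of 33 gene lists against 0 h, minus the median of all tested genes, with the number tested in brackets; circles are 24 h, triangles 48 h and squares 72 h, and filled symbols passed camera at its preset correlation. Tubular injury markers lie highest at 72 h, at 3.18, and S1 and S2 markers lowest, at -3.08; no list passed with an estimated correlation.

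Between successive times, Havcr1 rose again from 24 to 48 h (3.53), with Sprr1a (2.66), the interleukin-1 receptor antagonist Il1rn (2.02) and Ces2e (1.86). At the same step Serpina1f (-2.74), Cyp2d9 (-2.37), the anion transporter Slc22a7 (-2.18) and the cytochrome oxidase subunit Cox4i1 (-1.83) fell, at limma adjusted p from 1.1e-05 to 0.0357. From 48 to 72 h the fibrinogen chain gene Fgg (3.92), Coq10b (3.53) and Timd2 (3.42) rose most among genes with a fold change. Hbb-bs (-3.66), Hba-x (-2.89), Acmsd (-2.63) and the myo-inositol oxygenase gene Miox (-2.26) fell most, at limma adjusted p from 9.4e-08 to 0.0335. The row of Havcr1 overlaps that of Timd2, a neighbour of the same gene family. limma called 3046 rows from 24 to 48 h, 1200 higher and 1846 lower, or 1823 without 48 h library a and 1839 without 48 h library b; quantile normalisation gave 1576 higher and 1562 lower. From 48 to 72 h it called 5211, 3999 higher and 1212 lower, around a median of 0.18, and with the same median set in every library 2224 were higher and 2580 lower. Across the 4 times limma's F test called 9056 of 10757 rows.

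circRNAs are closed by a back-splice and lack free ends. The table held 2163 of them with a median span of 7810 bases on the genome, and detected numbers were alike between groups, from 1405 to 1620 per library (exact permutation p = 0.657, and 0.105 for at least 2 counts). The 10 most counted circRNAs made up 19.4% and 18.3% of counts at 0 h and 10.96% and 11.21% at 72 h. Of the 5 with the highest mean count, 1 with its ends in Ugt3a1 and Ugt3a2 (chromosome 15, 9311749 to 9365377, mm10) fell from 769 ± 60.7 normalised counts to 286 ± 20.1, 142 ± 2.37 and 66.7 ± 7.72 (SD, n = 2). Another, inside Aass, a lysine-degrading enzyme (chromosome 6, 23107140 to 23122737), fell from 424 ± 8.11 to 194 ± 8.99, 232 ± 13.5 and 149 ± 5.46. The most counted, inside the sodium-calcium exchanger gene Slc8a1 (chromosome 17, 81647809 to 81649638), had 785 ± 101, 765 ± 44.7 and 757 ± 72.2 normalised counts at 0, 24 and 48 h and fell to 382 ± 11.8 at 72 h (edgeR adjusted p = 1.1e-13). One inside Gigyf2 (chromosome 1, 87364104 to 87380008) rose at 24 h by a log2 of 0.58 (edgeR adjusted p = 0.0202), and 1 inside Rasa2 (chromosome 9, 96591950 to 96611499) passed at no time.

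At 24 h a circRNA inside Arhgap5 (chromosome 12, 52516079 to 52519967) rose from 25.8 ± 2.14 to 140 ± 13.2 normalised counts (log2 fold change 2.45 ± 0.261, SE). Its counts per library were 20 and 25 at 0 h, 133 and 152 at 24 h, 116 and 107 at 48 h, and 12 and 18 at 72 h. A circRNA inside Zfp644 (chromosome 5, 106618071 to 106638635) rose by 2.92 and 1 inside Strn3 (chromosome 12, 51647994 to 51661713) by 2.42. Those of Ugt3a1 and Ugt3a2 (-1.43) and of Exoc3l2 (chromosome 7, 19481246 to 19484734; -1.73) fell. In Cwf19l2 and Strbp 1 count in all at 0 h stood against 25 and 20 at 24 h, ratios of shares of 23.1 (95% counting interval 3.78 to 948) and 18.5 (2.95 to 766). Those inside Adgre1 (-3.32) and Rreb1 (-1.69) and 1 outside protein-coding genes (chromosome 10, 116953785 to 116964118; -3.46) were called lower. edgeR with Benjamini-Hochberg adjustment called 28 of 1574, 17 higher and 11 lower, with 171 at an unadjusted p under 0.05; it called 18 without 0 h library a and 12 without 0 h library b. The calls depend on the method: DESeq2 called 18, and limma without trend and robust called 0 at 24 h, 0 at 48 h and 2 at 72 h, those of Ugt3a1 and Ugt3a2 and of Cyp2j9 and Cyp2j5, and so lost 28 calls of named circRNAs. Single calls were lost in edgeR for Strn3 without 0 h library b (adjusted p = 0.1196) and for Exoc3l2 without 0 h b or 24 h b (0.0534 to 0.159). They were lost in edgeR for Cwf19l2 and the chromosome 10 circRNA without 0 h a, 0 h b or 24 h a (0.0928 to 0.333), and for Strbp without any of the 0, 24 and 48 h libraries (0.0534 to 0.555). edgeR also lost Adgre1 without 0 h a, 0 h b, 24 h b or 72 h a (0.0501 to 0.281) and Rreb1 without any library but 0 h b and 24 h b (0.0664 to 0.725). Strbp was also lost in limma with a pseudocount of 0.1 (adjusted p = 0.0652) and in edgeR without the low-count filter (0.0609). Rreb1 was lost in DESeq2 (adjusted p = 0.195) and in edgeR without the filter (0.0693), with the 2 groups alone (0.126), with the same circRNA total (0.0719) or median ratio (0.0591), and without circRNAs whose ends lie in 2 genes (0.0598).

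At 48 h the circRNAs of Arhgap5 that ends at 52519967 (1.96), Strn3 (2.66) and Ugt3a1 and Ugt3a2 (-2.43) were past the threshold, as was 1 with its ends in Cyp2j9 and Cyp2j5 (chromosome 4, 96583977 to 96658752), which fell from 379 ± 23.7 to 99.6 ± 12.5 normalised counts (-1.93). That of Cyp2j9 and Cyp2j5 was already lower at 24 h, at 188 ± 13.3 normalised counts (-1.01, edgeR adjusted p = 3.1e-07). Calls that single libraries ended were those inside Mlxipl (-1.17; without 48 h a, edgeR adjusted p = 0.103), Bnc2 (-0.99; without 0 h a or 48 h b, 0.0880 to 0.260) and Cep85 (2.97; without 0 h b or 48 h b, 0.260 to 0.705). So were those inside Lrmda (-4.12; without 0 h a, 48 h a or 48 h b, 0.112 to 0.255), Cwf19l2 (without 0 h a, 0 h b or 48 h a, 0.193 to 0.577), and a longer circRNA of Arhgap5 (2.18; without 0 h a, 0 h b or 48 h b, 0.0588 to 0.278), in edgeR adjusted p. The circRNAs of Mlxipl and Bnc2 were also called lower at 24 h (-1.22 and -1.33) and 72 h (-1.18 and -1.07), at edgeR adjusted p from 1.5e-06 to 0.00034. How these calls depend on single libraries is not reported here. A circRNA with its ends in the interferon-inducible genes Ifi211 and Ifi205 (chromosome 1, 173905473 to 174017656) had 1 count in all at 0 h and 29 at 48 h, a ratio of shares of 24.2 (95% counting interval 4.01 to 989). It was lost without 0 h a, 0 h b or 48 h a (edgeR adjusted p from 0.0773 to 0.144). DESeq2 called 11 circRNAs and lost this one (adjusted p = 0.232), Lrmda and Cep85 (0.233 for both), Cwf19l2 (0.336) and the longer circRNA of Arhgap5 (0.0981). limma with a pseudocount of 0.1 also lost Cep85 (adjusted p = 0.170). edgeR called 20, 13 higher and 7 lower, with 133 at an unadjusted p under 0.05; it called 12 without 0 h b and 11 without 48 h a.

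At 72 h the circRNAs of Cyp2j9 and Cyp2j5 (-3.73), Ugt3a1 and Ugt3a2 (-3.53), Aass (-1.51) and Slc8a1 (-1.04) were lower than at 0 h. A circRNA inside Tulp4 (chromosome 17, 6137211 to 6139156) stood at 118 ± 0.244 normalised counts, against 42.9 ± 3.01 at 0 h (1.47). The Tulp4 circRNA had stood higher still at 24 h (159 ± 63.4, 1.89) and 48 h (170 ± 6.64, 1.99), at edgeR adjusted p of 2.0e-15 and 2.0e-17. The circRNA of Arhgap5 that had risen was at -0.74 and did not pass. Further calls that single libraries ended were those inside Cd2ap (1.24; without 0 h b or 72 h a, edgeR adjusted p from 0.160 to 0.223), Aebp2 (2.48; without 0 h a, 72 h a or 72 h b, 0.0585 to 0.305) and Arhgap32 (-2.86; without 0 h a or 72 h a, 0.298 to 0.552). edgeR also lost 1 on the Y chromosome outside protein-coding genes (1.58; without 0 h b or 72 h a, 0.457 to 0.515), 1 on chromosome 16 (-1.95; without 0 h a or 72 h b, 0.189 to 0.328) and that of Ifi211 and Ifi205 (ratio of shares 17.0; without 0 h a, 0 h b, 48 h a, 48 h b or 72 h a, 0.0651 to 0.668). The last was also lost in edgeR without the low-count filter (adjusted p = 0.0686) and with the 2 groups alone (0.0515), and Arhgap32 in limma with a pseudocount of 0.1 (adjusted p = 0.0985). edgeR called 21, 6 higher and 15 lower, with 167 at an unadjusted p under 0.05. It called 13 without 0 h a or without 0 h b, 32 without 24 h b and 9 without 72 h a, and with every library scaled to the same circRNA total it called 14 higher and 11 lower. Across the 4 times edgeR called 43 circRNAs, or 68 without 24 h b.

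Set against the linear rows of their genes, most circRNAs could not be told from their host at this depth. Only 1 was called at all 3 times, that of Slc8a1, a marker of the distal convoluted tubule list: its linear row fell by 2.51, 2.99 and 2.19 on the log2 scale at 24, 48 and 72 h. The ratio of circRNA to linear RNA was higher by 2.47 ± 0.156, 2.94 ± 0.156 and 1.16 ± 0.156 (SE), at limma adjusted p of 5.3e-06, 8.0e-07 and 0.0138. Counts were scaled among circRNAs and FPKM among gene rows, so a shift of all circular against all linear RNA would not show in such ratios. Whether host rows also hold fragments from the circles' own exons was not tested. The ratio was also higher at 24 h for circRNAs inside Gab1 (2.41, limma adjusted p = 0.0283; counts of 4 and 9 at 0 h and 18 and 15 at 24 h) and Scaper (1.53, 0.0209). At 72 h it was higher for 1 inside Kmt2a (3.68, limma adjusted p = 0.0319), whose linear row also spans Tmem25 and Ttc36, and 1 inside Dnm3 (limma adjusted p = 0.0194), which had 0 counts at 0 h and 14 of 31773 at 72 h, a share at least 4.67-fold higher with 3 counts over the group as the floor. These 5 were named because they made up all calls of limma, 3, 1 and 3 of 1212 pairs with 790 hosts at the 3 times, with 171, 166 and 146 at an unadjusted p under 0.05. All were higher, but the counts depend on the filter and the pseudocount: over circRNAs above 0 in all 8 libraries limma called 8, 12 and 8, with 4 lower at each time, and a pseudocount of 0.1 gave 5, 2 and 1. At 24 h 1 call was left without 0 h a, 24 h a, 48 h a or 48 h b; at 48 h there were 6 without 24 h a or 24 h b; at 72 h there were 0 without 0 h b, 48 h a, 48 h b or 72 h a, 1 without 0 h a and 5 without 24 h a or 24 h b.

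Across the 328 circRNAs with a mean count of at least 10 and a tested host, Pearson's r between circRNA and host log2 fold changes was 0.34, 0.37 and 0.44 at 24, 48 and 72 h and Spearman's coefficient 0.35, 0.39 and 0.47; circRNAs are not independent replicates, and several share a host. Of these, 22, 22 and 19 had a host that fell by more than 2-fold, and their median changes were -0.28, -0.28 and -0.71, against -1.20, -1.34 and -1.32 for the hosts.

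**Figure D3:**
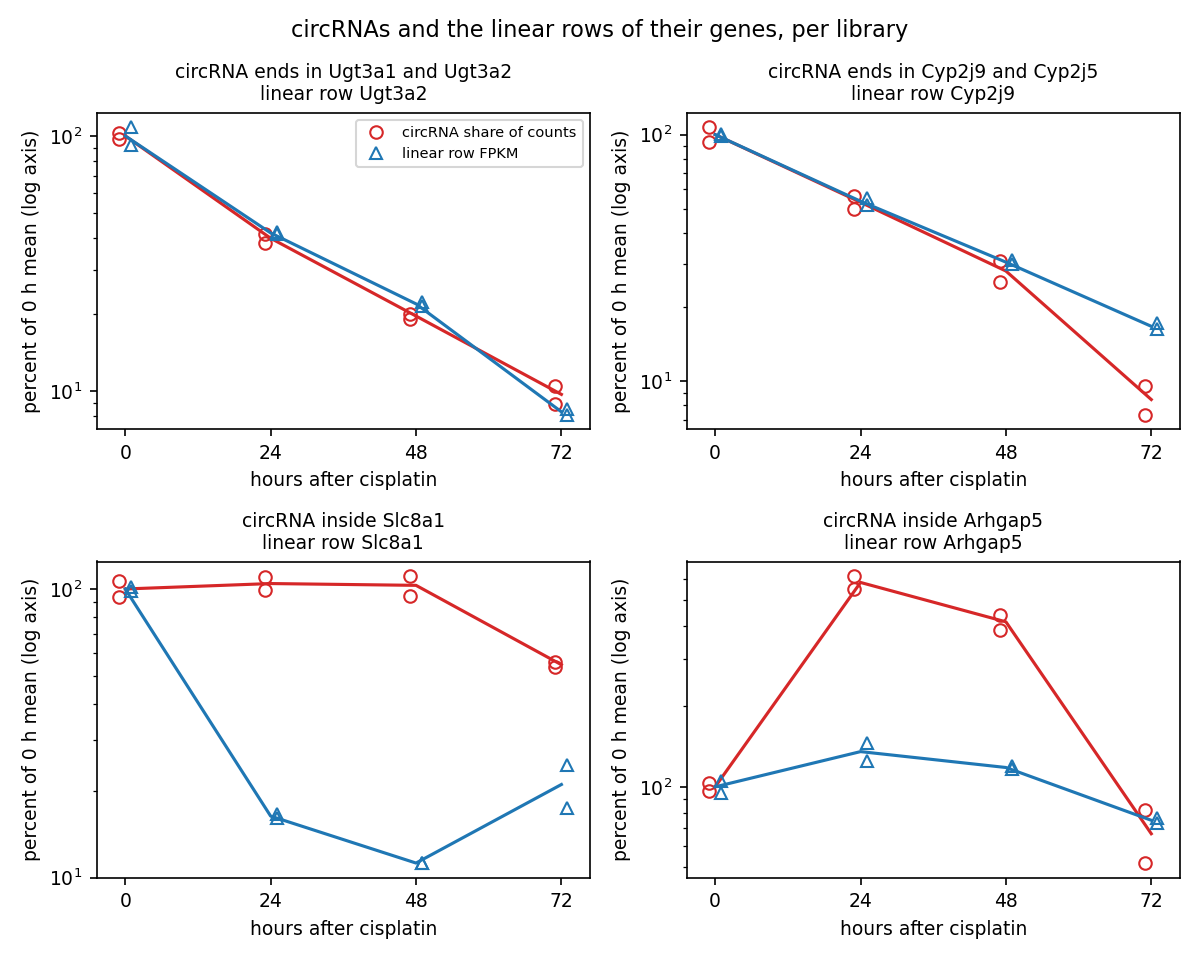
Share of circRNA counts (circles) and FPKM of the linear row (triangles) in each library, as percent of the 0 h mean (log axis), against hours after cisplatin; lines join the means of the 2 libraries. The circRNAs with ends in Ugt3a1 and Ugt3a2 and in Cyp2j9 and Cyp2j5 fell along with their linear rows, which span both genes, whereas the Slc8a1 circRNA stayed near its 0 h level until 48 h while the linear row fell by 2.99 on the log2 scale.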

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

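Tests over rows that keep to their own gene, DESeq2, circRNAs with both ends in 1 gene, the edgeR offset fit, the replicate block and lists without mt-Co1 were chosen after the results were seen; the other alternatives were set before the data were examined. Of 7683 values for named genes across the alternatives 7551 kept their direction and side of the threshold, 129 lost their call, 2 gained 1 and 1 reversed: Ddb1 at 24 h, from -0.33 to 0.0080 under quantile normalisation. For gene lists it was 1350 of 1473, with 78 lost and 45 gained, and for circRNAs 438 of 550, with 108 lost. The other 4 were group means of the number of circRNAs detected, which moved when detection asked for at least 2 counts. Requiring a mean of 5 FPKM, which tests fewer genes, gave 4974 calls at 48 h, 4829 at 72 h, 3368 from 48 to 72 h and 5716 in the F test. A change of at least 2-fold, by construction, left 1586, 2352, 2483, 171 and 452 calls in the 5 comparisons. Rows that keep to their own gene, of which there are fewer, gave 4244, 4523, 4570, 1757 and 3190, and 5473 in the F test. Leaving out each library in turn gave 1823 to 2870 genes from 24 to 48 h; here and below a lone library is assumed to vary like the other groups. camera with an estimated correlation called 0 of 99 list tests, against 60 at the preset correlation and 90 with fry. For circRNAs, limma without trend and robust called 0, 0 and 2 at 24, 48 and 72 h and 0 in the F test, and DESeq2 called 18 at 24 h, 11 at 48 h and 25 in the F test; the cause was not tested. Leaving out single libraries gave 12 to 29 circRNAs at 24 h, 11 to 24 at 48 h, 9 to 32 at 72 h and 29 to 68 in the F test. For circRNA against host, a pseudocount of 0.1 gave 5, 2 and 1 calls, circRNAs above 0 in all 8 libraries gave 8, 12 and 8, and the edgeR offset fit gave 41, 37 and 23; the cause was not tested. All calls of the first fit were higher, whereas 4, 4 and 4 were lower over circRNAs above 0 in all 8 libraries and 12, 8 and 12 in the offset fit. Leaving out single libraries gave 1 to 3, 1 to 6 and 0 to 5. The columns carry letters where the labels carry replicate numbers, and no label says that the letters pair the samples. The differences between a and b correlated between groups by -0.240 to 0.393 for genes and -0.0247 to 0.0368 for circRNAs, which for genes does not settle whether they do. With the letter as a replicate block limma called 7018, 7532, 7485, 2843 and 5049 genes in the 5 comparisons and 8991 in the F test, camera 60 list tests, and edgeR 26, 18 and 23 circRNAs and 41 in the F test. Against hosts the block left 2, 1 and 1 calls. It ended the camera call of the unfolded protein and integrated stress response at 24 h (adjusted p = 0.0592) and gave 1 for interstitial and mesangial markers at 48 h (0.0453). It also ended the edgeR calls of Strbp and Rreb1 at 24 h (adjusted p = 0.0621 and 0.0696), Cwf19l2 at 48 h (0.0595) and Ifi211 and Ifi205 at 72 h (0.0633). The circRNA fit with the same median was run as a median of ratios in edgeR, and its pseudocount fit in limma. The median circRNA had 4.25 counts per library.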

Other observations

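The tests of reads shared between paralogs, of counting noise and of error in the host values were chosen after the result was seen, as was the working definition of a host that fell; the other tests were set before.

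Genes with a long span on the genome fell more at 24 h: over 5 equal bins of 6454 genes by span the median log2 fold change went from 0.05 at a median span of 5.55 kb to -0.43 at 136 kb, and the share called lower from 30.0% to 57.6%; the bin of longest genes lay below that of the shortest by -0.623, adjusted for exonic length and mean expression (-0.595 to -0.651 over the 4 pairings of libraries), and by -0.590 at 48 h and -0.427 at 72 h. Exonic length bias is argued against for 24 h, since among genes of middling exonic length the difference was still -0.574 (-0.537 to -0.592); there it was -0.425 at 48 h and only -0.179 at 72 h (-0.140 to -0.197). Without adjustment the differences were -0.476, -0.307 and -0.168 in time order. These and the values for middling exonic length are differences of medians, whereas the adjusted values are differences of means from a linear fit. The size thus depends on how the difference is taken, most at 48 and 72 h, and the part due to the adjustment alone cannot be told. A block of transcription along long genes, which platinum adducts could cause, is left open, since the adjusted difference used as its test is the pattern itself.

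circRNAs followed their hosts' changes only in part: over 328 circRNAs the slope of circRNA on host log2 fold change at 72 h was 0.424 (bootstrap interval 0.319 to 0.556). Pearson's r over the same circRNAs was 0.444, so the low slope goes with a weak correlation. It does not show that circRNA changes were smaller in all. Independent error in the host values is argued against as the whole cause of the low slope. The slope was 0.442 (0.312 to 0.576) when the host change in each pair of libraries served as instrument for the other. Noise in the counts does not lower a slope on the host, so its tests could not have shown it as the cause and decide nothing. They gave 0.514 (0.326 to 0.725) over 40 circRNAs with a mean count of at least 50, and 0.922 to 1.09 in simulated tables, set before. Merged gene models as wrong hosts are argued against as the whole cause, since the slope over 220 circRNAs of rows that keep to their own gene was 0.506 (0.383 to 0.643), higher but below 1. A slower turnover of circular RNA met its test, which asked only for a rise in slope beyond its bootstrap SD. Over 92 circRNAs whose host fell at both times the slope rose from -0.0492 at 24 h to 0.207 at 72 h. That rise of 0.256 was little more than its bootstrap SD of 0.206 over hosts. Under 2 other definitions of a host that fell it rose by 0.349 (SD 0.264, from -0.32 to 0.03) and 0.455 (SD 0.217, from -0.28 to 0.17). The last of these sets holds the same 92, so it is no separate evidence. Over all 328 the slope did not rise (0.413, 0.355 and 0.424 in time order), so slower turnover is left open.

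The 2 circRNAs that fell furthest among the calls at 72 h, those of Ugt3a1 and Ugt3a2 and of Cyp2j9 and Cyp2j5, have their ends in 2 genes of 1 family. Of 9 tested circRNAs with such ends these 2 were called lower and 1, of Ifi211 and Ifi205, higher. Linear reads shared between paralogs and read as back-splices could give such falls. Over the 5 others with a tested linear row the slope on that row at 72 h was 0.989, but leaving out each in turn gave 0.241 to 2.24, on both sides of the interval of 0.450 to 0.679 for 1212 circRNAs inside 1 gene. With mean counts from 1.125 to 15.75 these 5 cannot tell whether this is the cause, and no biological explanation was tested.

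Some rows had values of 0 in single libraries of a group. Ints2 stood at 0 in both 0 h libraries, 24 h library a and 72 h library a, and at 125 FPKM in 24 h library b, 46.6 and 141 in the 48 h libraries and 146 in 72 h library b. Tex14 and Lig3 showed the same libraries at 0. Cornified envelope genes outside the rule for named genes, chosen after their values were seen, were Sprr2g, at 0.029 and 0 FPKM at 0 h and 15.5 and 17.6 at 72 h, and Crct1, at 0 and 0.031 at 0 h and 13.5 and 13.6 at 72 h.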
